A study of Homo sapiens with 2 samples.

How the data were processed

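Gene expression was measured in 2 RNA samples of the CAL-51 breast cancer line, 1 transfected with a negative control microRNA and 1 with a miR-4306 mimic, each for 48 h. Per the labels' protocols, RNA was extracted with TRIzol, checked on a denaturing gel, converted to biotin-labelled cRNA and hybridised to the array. The deposited values are probe set intensities on a linear scale, 1 column per array. The submitters' processing notes name MAS5, the Affymetrix algorithm that combines perfect match and mismatch probes into a signal. Its version, its target value and the way the arrays were scaled to each other are not given in the sources used here. Both deposited columns had the same median, so some scaling between the arrays had been applied. Such scaling assumes that most transcripts do not differ, and MAS5 signals are noisy at low intensity. The number of arrays limits the precision, and detection calls were not used here.

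Each column was assigned to its group from the sample labels. Of 54613 probe sets, 41091 carried a single gene symbol in the probe annotation, 1801 carried several, and 11721 were not listed there. Only probe sets with a single symbol entered gene values, and 41037 of them matched a gene of the current RefSeq table. Probe set names were taken from the platform annotation. The array had no control probe sets among the rows used here, so 3' to 5' ratios as a measure of RNA quality were not analysed here. A search for seed matches in 3' untranslated regions was not run, since no transcript sequences were used here. A further gene of the study-named list had no probe set with a single symbol and was not analysed here.

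Intensities were kept on the deposited scale, values under the 50th percentile of both arrays (11.4) were raised to that floor, and log2 was taken. A probe set was measured if its mean log2 signal over the arrays reached the floor, which left 22762 probe sets of 13308 genes. A gene's difference was the median over its measured probe sets of the log2 mimic signal minus the log2 control signal. With 1 array per group no test against replicate spread exists, and genes were counted at a threshold of 1.5-fold. A fold with 1 array at the floor, or one that a probe set at the floor could make larger, is a lower bound and is written "at least". The floor makes differences of dim genes too small.

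A total of 32 gene lists was described by the median difference of the measured members. Each median was placed as a percentile among 10000 random lists of the same size matched on mean signal in 10 bins. The central 95% of random medians, between percentiles 2.5 and 97.5, is called the range. This describes these arrays only. The lists were the study-named targets, published targets of miR-185-5p, vessel growth ligands and receptors, G1/S, G2/M, p53 targets, apoptosis, cholesterol, interferon and NF-kB. Further lists were epithelial and mesenchymal markers, invasion proteases, TGF-beta and BMP, hypoxia, glycolysis, oxidative phosphorylation, unfolded protein and amino acid stress, and NRF2. Others were heat shock, immediate early genes, ribosomal proteins, housekeeping genes, the microRNA pathway, DNA methylation, the EYA family and associated genes, and DNA repair. There were also 5 lists of cell type markers, for luminal and basal breast cells, fibroblasts, endothelium and leukocytes. A few genes stood in more than 1 list, such as KRT8 and KRT18 among epithelial and luminal markers. Both target lists and the shared seed were recalled from the literature. Of the lists fixed at the outset 1 is not reported here.

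Genes were named by a rule with 4 parts. The rule took the 12 highest and 12 lowest genes with at least 2 probe sets above the floor on both arrays and all of these in the same direction, ranked by the least different of them. It took every measured member of both target lists. From each other list it took up to 4 members with the largest difference past 1.5-fold, or the 2 largest where none passed. It took up to 4 genes per direction with the largest bound, among genes with every probe set above the floor on 1 array and at the floor on the other. Other genes in the text were chosen after their values were seen, namely PLK1, UBE2C, CDC20, CCNB2 and those of the closing part.

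The floor, the threshold, the lists, the rule and the alternatives were fixed before the data were examined. The alternatives were equal medians, quantile scaling, loess of the log2 difference on mean log2 signal (span 0.3), the floor as a pseudocount, floors at the 30th and 65th percentile, the brightest probe set or the mean per gene, leaving out probe sets marked as cross-hybridising (_x_at and _s_at), a 2-fold threshold, and random lists without matching. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

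The gene and list steps were tested on simulated data over 13305 genes, with noise set to the spread between probe sets of a gene (SD 0.423 on the log2 scale). Of genes changed 2-fold, 85.7% passed 1.5-fold in the right direction, and of genes changed 4-fold, 100%. Of unchanged genes, 9.89% passed 1.5-fold, so single genes near that threshold are uncertain. The SD came from probe sets above the floor on both arrays and was used at all signals. It leaves out differences shared by a gene's probe sets, such as those between cultures, so the real share could be larger. Of 200 random lists without a shift, 6.5% fell outside the range.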

Results

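CAL-51 cells, a human triple-negative breast cancer line, had been transfected for 48 h with a negative control microRNA or with a mimic of the microRNA miR-4306. Total RNA of each culture was hybridised to 1 Affymetrix HG-U133 Plus 2.0 array, a 3' expression array that reports signals for sets of short probes. The series thus held 2 arrays, 1 per group. Each array gave a signal for 54613 probe sets, with the same median of 11.4 on both. The lower and upper quartiles of the signals were 5.44 and 34.6 on the control array and 6.02 and 30.4 on the mimic array. Across probe sets, which are not independent replicates, the log2 signals of the arrays correlated with a Pearson r of 0.962 and a Spearman correlation of 0.933. After low signals were raised to a floor, 13308 genes were measured.

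The design compared the mimic array with the control array and asked which mRNAs differed 48 h after miR-4306 was supplied. The genes with the largest differences stood lower on the mimic array. Among genes with at least 2 probe sets above the floor on both arrays, the lowest was CDC42, a small GTPase that controls cell polarity and movement, at least 8.71-fold lower. In this class ACTR3, a subunit of the Arp2/3 complex that nucleates branched actin, was 8.34-fold lower, and RAC1, a small GTPase of cell migration, was 5.09-fold lower, though some genes with fewer such probe sets differed more than RAC1. Transcripts of mitosis and of DNA repair were lower as groups than random genes of like signal. Higher signals were fewer and smaller. CHAC1, a gene of the amino acid stress response, was 4.85-fold higher, and among genes with at least 2 probe sets the heat shock genes HSPA6 and DNAJB1 were 2.86-fold and 2.41-fold higher.

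In total 2105 genes were at least 1.5-fold lower on the mimic array and 759 at least 1.5-fold higher, together 21.5% of the genes measured, and 73.5% of them lay on the lower side. This split moved with the scaling between arrays. Loess scaling gave 1623 lower and 1123 higher genes, 59.1% lower, and quantile scaling gave 1454 lower and 1309 higher genes, 52.6% lower. Quantile scaling moved the median of all genes by 0.12 on the log2 scale relative to the deposited values. Counted relative to the median gene, the deposited values gave 1812 lower and 977 higher genes. With all 3 scalings, 1454 genes were lower and 759 were higher. Over the floors, the pseudocount and the scalings tried, the count of higher genes ranged from 311 to 1309. At a 2-fold threshold the deposited values gave 605 lower and 118 higher genes, and at a 4-fold threshold 21 lower genes and 1 higher gene.

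**Figure D1:**
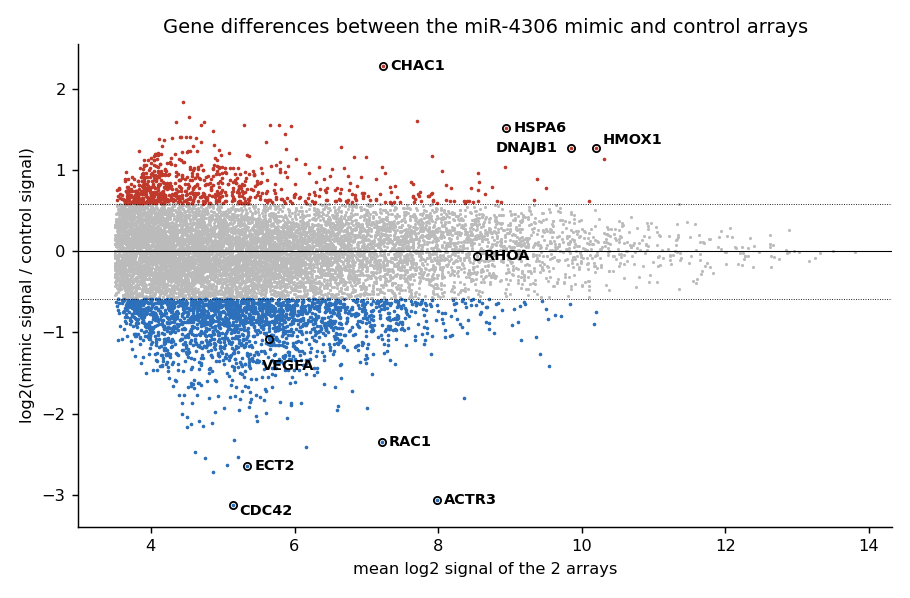
Each point is 1 of the 13308 measured genes, with its mean log2 signal over the 2 arrays on the x axis and its log2 ratio of mimic to control signal on the y axis. Blue points (2105 genes) were at least 1.5-fold lower and red points (759 genes) at least 1.5-fold higher on the mimic array, dotted lines mark that threshold, and circles mark named genes, of which CDC42 and ACTR3 lie lowest.

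There was 1 array per group, so the differences have no replicate check and no p-value is given. Probe sets of the same gene are repeated measurements of the same RNA. Among 5222 genes with at least 2 probe sets above the floor on both arrays, the differences of 2 probe sets of a gene correlated across genes with a Pearson r of 0.374, and 62.8% of pairs had the same direction. All of a gene's probe sets above the floor on both arrays were at least 1.5-fold lower for 314 of these genes and at least 1.5-fold higher for 24.

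CDC42 and VEGFA had been named by the group that studied this line as targets of miR-4306, so their direction is not independent evidence. Both were lower on the mimic array. For CDC42, the signal on 1 probe set was 274 on the control array and 18.1 on the mimic array, a 15.2-fold difference. Another had 80.5 and 16.1, a log2 difference of -2.32. On the remaining CDC42 probe sets that were measured the mimic signal lay below the floor, and the control signals of 244 and 15.2 were at least 21.4-fold and at least 1.34-fold higher. The gene's 8.71-fold difference therefore rests in part on bounds. VEGFA, which encodes the main growth factor for blood vessels, was 2.13-fold lower. Its probe sets gave 2.59-fold, 1.75-fold and 1.53-fold lower signals, and for 1 more, at the floor on the mimic array, at least 2.62-fold. The median log2 difference of this pair of genes was -2.11, at percentile 0.01 of random lists matched on signal.

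**Figure D2:**
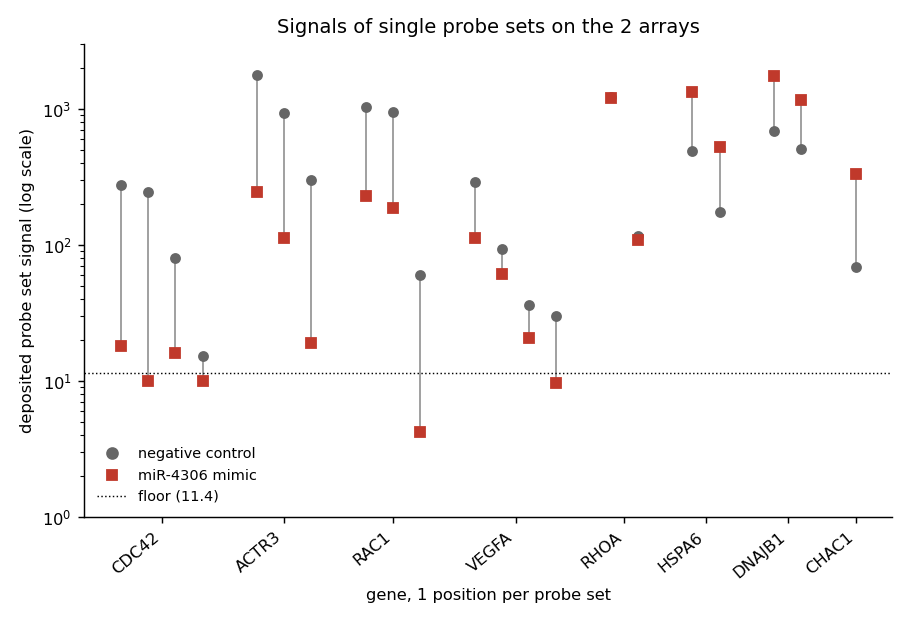
Deposited signals on a log scale for the counted probe sets of 8 genes, with 1 position per probe set on the x axis, grey circles for the control array and red squares for the mimic array. The 3 probe sets of ACTR3 had control signals of 1775, 940 and 300.4 and mimic signals of 245, 113 and 18.9, while the probe sets of HSPA6, DNAJB1 and CHAC1 were higher on the mimic array.

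MicroRNA miR-185-5p is reported to share its seed, the stretch that pairs with target mRNAs, with miR-4306, which was not checked here. Of 14 genes published as miR-185-5p targets, 11 were measured, and 0 were at least 1.5-fold lower or higher by the median of their probe sets. The list's median was 0.13, at percentile 90.7, but at percentile 42.1 with the brightest probe set per gene. The small GTPase RHOA differed by -0.06, and the DNA methyltransferase DNMT1 by -0.07. With quantile scaling these values were 0.02 and 0.01. CDK6 at -0.54 and CORO1C at -0.50 were the lowest of the list, and HMGA1 at 0.48 the highest. The kinase AKT1 stood at 0.19, STIM1 at 0.07, SREBF1 and SREBF2, the regulators of lipid synthesis, both at 0.22, SCD at 0.14 and EPAS1 at 0.13. Probe sets of CDK6, SREBF2, SCD and EPAS1 disagreed in direction, and the brightest stood at -0.88 for CDK6, -0.59 for SCD and -0.29 for EPAS1. CDK6 probe sets with control signals of 325, 83.7 and 68.2 were 1.85-fold, 2.13-fold and 2.17-fold lower. Its other measured probe sets had control signals of at most 17.5, and the only higher one went from 15.0 to 24.8.

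Genes of G2/M and mitosis had a median of -0.44 over 29 measured members, at percentile 0.04, with 14 at least 1.5-fold lower and 0 higher, and with loess scaling 12 and 0. The kinesins KIF23 and KIF11 were 3.65-fold and 2.99-fold lower. TTK, a spindle checkpoint kinase, was 3.54-fold lower, and TOP2A, the topoisomerase that untangles sister chromatids, 2.85-fold lower. Other mitotic genes lay nearer 0, and PLK1 stood at -0.13, UBE2C at -0.10, CDC20 at 0.01 and CCNB2 at 0.28, with CCNB2 probe sets that disagreed, at -0.23 and 0.78. The G1/S and DNA replication list was inside the central 95% range of matched lists, with a median of -0.12 over 28 genes at percentile 16.0. In it CCNE2 was 2.43-fold and MCM10 1.73-fold lower, and CCNE1 1.52-fold higher. MCM10 and CCNE1 were no longer past the threshold with the pseudocount. CCNE1 was also not past it with the floor at the 30th percentile, nor MCM10 without _x_at and _s_at probe sets. DNA damage repair genes had a median of -0.51 over 14 measured members, at percentile 0.93, with 5 lower and 0 higher, and with loess scaling 4 and 0. ATR, the kinase that senses stalled replication forks, was 3.62-fold lower, BLM 1.86-fold, CHEK1 1.73-fold and BRCA1 at least 1.85-fold.

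All 3 measured RAC1 probe sets were lower, at 1029 against 228, 956 against 188, and for the dimmest at least 5.31-fold. Further genes named on the lower side by the rule for repeated probe sets were CHMP2B, an ESCRT-III component, at 3.48-fold, the splicing regulator MBNL1 at 3.25-fold, the chromatin remodeller CHD1 at 3.15-fold and the cohesin subunit SMC3 at 3.18-fold. MIB1, a ubiquitin ligase of Notch signalling, was 2.78-fold lower. TRIM24 was 3.20-fold lower, but its measured probe sets were all marked as cross-hybridising (_x_at). Another TRIM24 probe set, too dim to be measured, went from 7.52 to 12.8. MCL1, which protects cells from apoptosis, was at least 3.16-fold lower. Among probe sets above the floor on both arrays, the least different of these genes still differed by between 2.55-fold for MCL1 and 3.46-fold for CHMP2B. On the higher side, by the same rule, HTRA3 was 1.94-fold, ZFPM1 1.96-fold, TMEM259 1.93-fold and DPF1 1.84-fold higher. SESN2, a stress-induced sestrin, was 1.78-fold higher, HILPDA 1.75-fold, the receptor EPHB4 1.69-fold, the long noncoding RNA MEG3 at least 1.69-fold, SHROOM1 at least 1.66-fold and JMJD6 1.62-fold. Among genes with every probe set above the floor on 1 array and at the floor on the other, 389 were lower and 539 higher on the mimic array. The largest bounds in this class were at least 5.53-fold lower for NUF2, a kinetochore protein, 4.36-fold for NTN4, 3.67-fold for CHUK, a kinase of the NF-kB pathway, and 2.79-fold for NCEH1. Those on the higher side were 2.60-fold for MED14OS, 2.34-fold for FGF21, 2.30-fold for RNASE2CP and 2.27-fold for C11orf42.

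Of the 32 lists reported, 5 lay outside the central 95% range, 3 below and 2 above. Apart from the study-named pair they were 4 of 31, where 1.55 would be outside by chance if members varied like unrelated genes. Members of a list can differ together between 2 cultures, so this number can be too low. The 2 above were immediate early genes and glycolysis. Immediate early genes had a median of 0.26 over 23 members, at percentile 99.9, with members on both sides, 5 higher and 4 lower. ZFP36, which destabilises AU-rich mRNAs, was 2.25-fold higher and the phosphatase DUSP5 1.66-fold higher, whereas SPRY2, an inhibitor of growth factor signalling, was 2.39-fold and MYC 1.80-fold lower. Glycolysis genes had a median of 0.24 over 16 members, at percentile 99.2, with 14 of them above 0. The enolase ENO2 was 1.59-fold and the phosphofructokinase PFKL 1.53-fold higher, the latter 1.35-fold on its brightest probe set. Under loess and quantile scaling the glycolysis list was back inside the range, at percentiles 95.5 and 95.8.

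**Figure D3:**
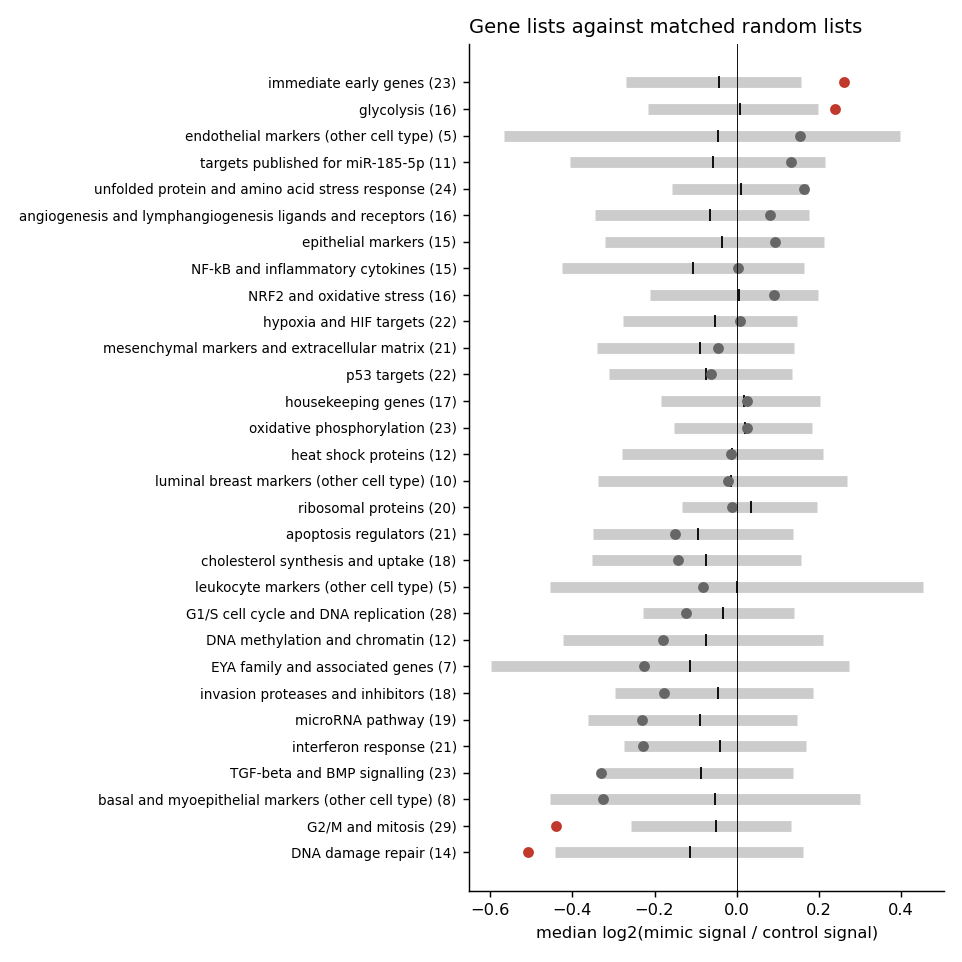
Median log2 ratio of mimic to control signal (x axis) for each gene list with at least 5 measured genes, with the number measured in brackets. Points are the lists' medians, grey bars the central 95% range of 10000 random lists matched on signal, black ticks their median, and red points lie outside the range, from -0.51 for DNA damage repair to 0.26 for immediate early genes.

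Stress genes did not move together. In the unfolded protein and amino acid stress list 4 of 24 genes were higher and 3 lower, and the median of 0.16 was at percentile 96.7. CHAC1 was higher by 2.28, from a signal of 68.5 to 332, and SLC3A2, a subunit of amino acid transporters, by 0.96. The endoplasmic reticulum chaperones DNAJC3 and HSP90B1 stood at -1.44 and -1.33. NRF2 and oxidative stress genes had a median of 0.09, at percentile 79.9, with 3 higher and 1 lower. HMOX1, the heme oxygenase, was 2.41-fold and OSGIN1 1.95-fold higher, SLC48A1 1.51-fold higher and ME1 1.53-fold lower, the last no longer past the threshold with loess scaling. Heat shock proteins, a list without HSPA6, had a median of -0.01, at percentile 49.0, with DNAJB1 and BAG3 at 1.27 and 0.89 and CRYAB at -0.67. HSPA4 stood at -0.60 with probe sets that disagreed, between -0.95 and 0.40. With loess scaling 2 of these genes were past the threshold on the higher side and 0 on the lower.

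TGF-beta and BMP signalling genes had 8 of 23 members lower and 0 higher, against 7 lower and 2 higher with loess scaling. The median of -0.33 lay at percentile 2.56, just inside the range, but outside it, at percentile 1.08, with the brightest probe set per gene. The receptors TGFBR2, TGFBR3 and TGFBR1 were 2.69-fold, 2.21-fold and 2.09-fold lower and SKIL, which represses SMAD proteins, 2.49-fold. With the floor at the 30th percentile TGFBR2, TGFBR1 and SKIL were no longer past the threshold. The TGFBR1 value comes from a bright probe set at 3.70-fold and a dim one at 1.18-fold lower. TGFBR1 was also not past the threshold without _x_at and _s_at probe sets. Blood and lymph vessel ligands and receptors other than VEGFA had a median of 0.08 over 16 genes, at percentile 87.4, with 3 higher and 3 lower. Endothelin 1 (EDN1) was 2.85-fold and THBS1 2.24-fold lower, and adrenomedullin (ADM) 2.05-fold and HGF 1.97-fold higher. The brightest EDN1 probe set was only 1.20-fold lower. HGF rests on 1 dim probe set, at 14.5 and 28.7, and was not past the threshold with the floor at the 65th percentile. Hypoxia genes were balanced, with 4 higher and 4 lower of 22, a median of 0.01 and percentile 71.5. Among them BNIP3L was 2.26-fold, EGLN1 2.10-fold and HIF1A 2.01-fold lower.

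Epithelial markers had 2 higher and 2 lower of 15 genes, with a median of 0.09 at percentile 83.3. OCLN, a tight junction protein, was 1.95-fold and OVOL2 1.63-fold higher, CLDN3 was at least 1.55-fold lower, and the probe sets of ELF3, at -0.64, disagreed in direction. The OCLN and OVOL2 values each rest on 1 dim probe set, with a control signal of 12.7, and OVOL2 was not past the threshold with the pseudocount. Mesenchymal and matrix genes had 5 lower and 0 higher of 21, with a median of -0.05 at percentile 62.9. With loess scaling they had 5 lower and 2 higher and a median of 0.10. LOX, which crosslinks collagen, was 2.47-fold lower, and the transcription factors SNAI2 and ZEB1 were 1.94-fold and 1.70-fold lower, with FBN1 at 1.77-fold, and with quantile scaling ZEB1 was no longer past the threshold. Invasion proteases and inhibitors had a median of -0.18 over 18 genes, at percentile 14.3, with ADAM9 2.21-fold and ADAM10 1.88-fold lower and 0 higher. With the floor at the 30th percentile ADAM9 was no longer past the threshold.

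The p53 target list had a median of -0.06 over 22 genes, at percentile 54.1, with 2 higher and 4 lower, and a median of 0.07 with loess scaling. FAS was 2.36-fold and RRM2B at least 2.67-fold lower, and MDM2 stood at -1.12 with probe sets that disagreed, between -1.39 and 0.04. Apoptosis regulators had a median of -0.15 over 21 genes, at percentile 31.7, and 4 were lower, among them MCL1 and the caspase inhibitors XIAP at least 1.96-fold and BIRC2 1.52-fold. With loess scaling the median was 0.08, at percentile 71.2, with 3 lower and 1 higher, and BIRC2 was no longer past the threshold. The probe sets of CASP6, at -0.71, disagreed in direction, each with 1 array at the floor. Interferon response genes, which can respond to transfected double-stranded RNA, had a median of -0.23 over 21 genes, at percentile 5.53, with 5 lower and 1 higher. HERC5 was 2.06-fold, IFIT5 1.58-fold and IFIT1 at least 1.67-fold lower, and RIGI at least 1.85-fold higher. The IFIT1 and RIGI values each rest on 1 dim probe set, with 1 array at the floor. With loess scaling the list had 3 lower and 1 higher, at percentile 25.5, and IFIT5 was no longer past the threshold. NF-kB and inflammatory genes had a median of 0.00 over 15 genes, at percentile 78.5, with NFKB1 1.68-fold, TNFAIP3 1.63-fold and SOD2 1.55-fold lower. With loess or quantile scaling 0 of these 3 genes were past the threshold.

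Genes of the microRNA pathway had a median of -0.23 over 19 members, at percentile 14.5. PAN3, a deadenylase subunit, was 2.75-fold and the decapping enzyme DCP2 2.18-fold lower, PRKRA 1.51-fold, and DICER1 at least 1.84-fold, of which PRKRA was not past the threshold with loess scaling. In the cholesterol list, with a median of -0.14 over 18 genes at percentile 30.7, SC5D was 2.10-fold, HSD17B7 1.69-fold and STARD4 1.61-fold lower, and MVD 1.60-fold higher. STARD4 was not past the threshold with loess scaling, and the list's median was then 0.02. DNA methylation and chromatin genes had a median of -0.18 over 12 genes, at percentile 25.4, with HELLS at least 1.90-fold and SUZ12 1.68-fold lower, the latter not past the threshold with quantile scaling. In the list of the EYA family and associated genes, with a median of -0.23 over 7 genes at percentile 30.4, the cofactor EYA4 was 2.59-fold lower and MYOG at least 1.89-fold higher. Oxidative phosphorylation genes had a median of 0.02 over 23 genes, at percentile 51.6, and SDHD at 1.56-fold lower was the only member past the threshold, and with loess scaling 0 were.

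Control classes and cell type markers lay inside the range, though fibroblast markers moved above it with the floor at the 30th percentile. None of 20 ribosomal protein genes or 17 housekeeping genes reached 1.5-fold, and their medians were -0.01 and 0.02, at percentiles 29.7 and 52.5. With loess scaling 1 housekeeping gene was past it. RPL3 stood at 0.28 and TBP at 0.49. The values of RPLP1 (0.50) and PPIA (0.52) rested on dim probe sets on the higher side, while the bright ones stood at -0.11 and -0.05. Luminal breast markers were at percentile 48.3, with a median of -0.02, GATA3 at 0.60 and TFF1 at the floor on the control array. Basal and myoepithelial markers were at percentile 8.25 with a median of -0.33 and MYLK 1.85-fold lower. Fibroblast markers were at percentile 72.7, with a median of 0.04, DCN at -0.37 and PDGFRB at 0.16. Endothelial markers were at percentile 80.9, with a median of 0.15 and EGFL7 1.89-fold higher. Leukocyte markers were at percentile 34.1, with a median of -0.08, CD3E at -0.41 and TYROBP at the floor on the mimic array.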

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

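The tests of scaling, of probe set noise and of an equal drop of the G2/M and G1/S lists were chosen only after the result was seen.

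Probe sets without a single gene name entered no gene value, and of the 13522 such probe sets 3872 were above the floor on both arrays, among which 76 were at least 2-fold higher on the mimic array than on the control array and 151 at least 2-fold lower.

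More genes were lower than higher on the mimic array, 2105 against 759 at 1.5-fold. At 1.5-fold the excess cannot be told apart from scaling between the arrays, because the lower share was 52.6% with quantile scaling, close to an even split, but 59.1% with loess. At 2-fold it was 63.2% with quantile scaling and 69.3% with loess, which argues against scaling as the whole cause. Over 20 random picks of 2 probe sets per gene, both were at least 1.5-fold lower in a median of 419 pairs, against at most 237 in shuffled pairs. This argues against noise of single probe sets as the whole source of the lower genes. Shuffling was not matched on signal and keeps more lower than higher values, so it cannot say where the excess comes from. For the higher genes such noise stays open, with 34 pairs against at most 30. Depending on the probe sets picked, that count of 34 ranged from 29 to 38. Lowering of many transcripts by the mimic may add to the excess, as a hypothesis, but RNA quality and differences between the 2 cultures were not tested.

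Mitotic genes were lower as a list, at percentile 0.04. After loess the list was at percentile 0, but the matched lists share any trend with signal, so this could hardly change. The list's own median was -0.44 as deposited and -0.38 after loess, which argues against intensity-dependent scaling as the whole cause. Without cross-hybridising probe sets (18 genes) the list was again at percentile 0, which argues against cross-hybridisation as the whole cause. The G2/M median minus the G1/S median was -0.32, at percentile 1.31 of random pairs of matched lists, which argues against an equal drop of these lists. The DNA damage repair list was also low, with a median of -0.51, so a drop beyond mitotic genes stays open. A smaller share of cells in mitosis on the mimic array could give such a gap, but the share of cells per phase was not measured here. Of the 29 members 23 were below 0 and 6 above, a count that cannot decide this. Differences in cell density or in RNA quality between the cultures stay open and were not tested.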

How the results depend on the processing

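No setting in this part was chosen after the results were seen. Equal medians changed nothing, since the deposited medians were already equal, so that setting tests nothing and is not counted here. Under the other alternatives 235 list results stayed inside or outside the range as reported and 8 did not. A list inside the range counted as kept even if its direction relative to matched lists changed. Apoptosis regulators did so, from percentile 31.7 to 71.2 with loess scaling. The G2/M, DNA repair and immediate early lists stayed outside the range under every alternative, and so did the study-named pair, of which only CDC42 was left without _x_at and _s_at probe sets. The G2/M list's excess over matched lists lay between -0.69 and -0.35. The count of higher genes was 1309 with quantile scaling, 311 with the floor as a pseudocount, 1192 and 483 with the floor at the 30th and 65th percentile, and 118 at 2-fold. The count of lower genes was 1365 with the pseudocount and 605 at 2-fold. A pseudocount and a higher threshold shrink counts by construction, and a lower floor admits more dim genes. The excess of the glycolysis list over matched lists was 0.23 as reported and, no longer outside the range, 0.18 with quantile, 0.18 with loess scaling and 0.17 without _x_at and _s_at probe sets. The TGF-beta and BMP list moved outside the range with an excess of -0.20 with the pseudocount, -0.25 with the 30th percentile floor, -0.32 with the brightest probe set and -0.27 without matching, and the unfolded protein and amino acid stress list with 0.23 without matching. MDM2 turned to 0.083 with the 30th percentile floor and 0.043 with its brightest probe set, and ELF3 to 0.31 with its brightest probe set, where probe sets of these genes disagree. For the list changes the cause was not tested. Among other named gene values 846 moved by less than the spread of the gene's probe sets, or of probe sets in general for a gene with 1, and 69 by more. The 846 include values that could not move. For a gene with 1 measured probe set, the brightest and the mean are the reported value, and with 2 the mean is. Of the 102 named genes past 1.5-fold, 14 were no longer past it with quantile and 12 with loess scaling. With the pseudocount 23 were no longer past it, and with the 30th percentile floor 14, among them THBS1, LOX, ADAM9 and SC5D. The brightest probe set took away 5, among them EDN1 and PFKL, and the mean 2. With the 65th percentile floor 91 were measured, of which 3 were no longer past it. Without _x_at and _s_at probe sets only 70 were measured, of which 4 were no longer past it. ATR, KIF23, DNAJB1, SMC3, MBNL1, TRIM24, SESN2 and HSP90B1 then had no measured probe set. Of the marker list results 43 stayed inside the range, and fibroblast markers moved above it with the 30th percentile floor, at 0.40. The seed site search and its alternatives were not run. Signals near the floor limit how large a difference of a dim gene can appear.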

Other observations

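The genes, the symbol families and the split of the stress list in this part were chosen only after the result was seen. Several genes outside the naming rule were far lower on the mimic array, each with 1 measured probe set. At least 1 other probe set each of IL6ST and SEMA3C was below the floor on both arrays. IL6ST, the shared receptor of interleukin 6 family cytokines, was at least 6.60-fold lower, and SEMA3C, a secreted guidance factor, at least 5.85-fold lower. ECT2, an exchange factor needed for cytokinesis, was 6.27-fold lower. YOD1, a deubiquitinating enzyme, was 6.20-fold, the secreted protein FAM3C 5.79-fold and HPS5 5.34-fold lower. The kinase MAP3K1 was 4.16-fold and the receptor ROBO1 3.82-fold lower. EPS8 and TWF1, which bind actin, were 3.73-fold and 3.72-fold lower. On the higher side KLK15, a kallikrein protease, was 3.57-fold, TCAP 3.14-fold and SERPINH1, a collagen chaperone, 3.03-fold higher.

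Genes that share the start of their symbol were grouped into 57 families of at least 20 measured genes. Of these 6 had medians below the range of matched lists and 1 above. By chance 1.43 would lie on each side if members varied like unrelated genes, a number that can be too low. Nucleoporin genes (NUP) had a median of -0.49 over 23 genes, at percentile 0.17, and 9 were at least 1.5-fold lower against 1 higher. NUP54 was 2.35-fold, NUP133 1.86-fold and NUP205 1.76-fold lower, and NUP188 was 1.61-fold higher. After loess and quantile scaling the family was at percentiles 0.19 and 0.17. The kinesins (KIF) had a median of -0.27 over 36 genes, at percentile 1.61, with 12 lower and 1 higher, and share KIF11, KIF20A, KIF23 and KIF2C with the G2/M list. The F-box genes (FBXO) were at -0.31 over 31 genes and the ZBTB zinc finger genes at -0.32 over 38. The CDC genes, at percentile 0.51 over 31 genes, and the 286 ZNF genes, at percentile 0.20, were also below, and the 223 LINC genes were above, at percentile 97.6. The CDC genes are no separate group, since they include CDC42 and, from the G2/M and G1/S lists, CDC20, CDC25A, CDC25B, CDC25C and CDC6. With loess and quantile scaling all of these families stayed outside the range. The 266 SLC genes, at percentile 92.3 as deposited, then moved above it, at 98.4 with loess and 99.6 with quantile scaling. The 35 RBM genes moved below it with quantile scaling only, at percentile 2.035.

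Within the stress list, of 14 amino acid stress genes 13 were above 0, with a median of 0.44 and 4 at least 1.5-fold higher. The 10 folding genes of the endoplasmic reticulum had a median of -0.07, with 7 below 0 and 3 at least 1.5-fold lower. With loess scaling the medians were 0.48 and -0.04, and with quantile scaling 0.50 and -0.02.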
